A study of Mus musculus with 8 samples.

How the data were processed

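Total RNA from mouse kidney was measured on 8 single-colour Agilent microarrays of mouse miRNAs, 1 array per sample. Per the labels, 4 samples came from control mice and 4 from db/db mice, all males aged 28 weeks, and 100 ng of total RNA was labelled with Cy3 for each array. The number in each title was used as the replicate number. The array titles and the source and strain labels name the controls differently, as dbm and as m/m, so whether the controls carried a db allele was not settled here. The labels do not say for each sample that it came from a separate animal, so p-values measure the spread between these samples.

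The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 12.0.3.1, per the file headers and the submitters' processing notes. Per the file headers, spatial detrending of the spot signals was on, background correction was off and no probes were used for dye normalization. Flags in the same files mark outlier spots, saturated spots, probes well above background and miRNAs called detected. Each array carries 58594 spots, of which 56430 belong to 4415 probes of 1881 mouse miRNAs. No miRNA spot was saturated on any array. All 8 arrays lay on 1 slide and came from 1 scan. Row 1 of the slide held the 4 control samples and row 2 the 4 db/db samples, so slide row and genotype cannot be told apart.

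The authors also deposited a table of values with a linear ratio for each miRNA and array. Its scale, centring and direction were read from the values. For the miRNAs compared, its log2 change between the groups had a correlation of 1 (across miRNAs, which are not independent replicates) with that of the gene total signal of the scanner files and lay 0.17 below it, so a higher value means more signal. Each miRNA had been divided by a value of its own, and each array by a factor of its own. How that factor was chosen is not given in the sources used here. The medians of the columns were 1.11, 1.10, 1.10 and 0.980 in control replicates 1 to 4, and 0.857, 1.01, 0.994 and 0.947 in db/db replicates 1 to 4. In the gene total signal an undetected miRNA holds a fill of 0.1. Where a miRNA was undetected on some arrays, its change in the table can be inflated. The table was used only as an alternative.

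From the scanner files, the processed signal was averaged over the spots of a probe that were not outliers and then over the probes of a miRNA, on the linear scale. Each array was scaled so that the 75th percentile of the 269 miRNAs detected on all 8 arrays was equal. Scaled signals under a floor of 2.80, the median over arrays of the lowest scaled signal of a detected miRNA, were set to that floor, which is 1.48 on the log2 scale. The 316 miRNAs detected on all 4 arrays of at least 1 group were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on log2 values, with the R package data.table, version 1.17.8, for reading and writing files. Calls were made at an adjusted p under 0.05 after Benjamini-Hochberg adjustment, 2-sided. The number of arrays limits the precision of every value. A miRNA not detected on any array of a group has only a bound there. Its fold is given as at least the mean of the brighter group against the mean over the dim arrays of the highest of 3 values: the lowest signal of a detected miRNA on that array, the floor and the miRNA's own signal.

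A total of 19 lists of miRNAs by family, cell type or process was fixed before the data were examined. The 15 lists with 3 or more tested members were tested with camera in limma, with its preset correlation of 0.01, and again with an estimated correlation. fry was run beside it. It asks whether the members of a list move, on balance, one way, and does not compare a list with other miRNAs. miR-192-5p stands in 2 lists, the tubule-enriched and the fibrosis-associated one. Differences of array-wide measures were tested with an exact permutation test over the 70 assignments of 8 arrays to 2 groups of 4, 2-sided, for which the smallest p is 0.0286.

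The rule for the miRNAs named was also fixed before the data were examined. It took the 12 largest increases and the 12 largest decreases among called miRNAs with no overlap between the groups, and up to 4 members of each list, called ones first. It added up to 6 miRNAs detected on all arrays of 1 group and on none of the other, ordered by the bound of their fold, and the other arm of each miRNA so named if tested. If fewer than 5 miRNAs had passed in a direction, the 5 with the smallest p would have been named and said not to have passed; this was not needed. In all, 91 miRNAs were named by the rule. Members of a family that differ by few bases are open to cross-hybridisation.

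The steps were tested on simulated data for the 316 miRNAs, with the real means and spreads and 200 changed miRNAs in each of 20 runs. For the comparison of db/db with control, changes of 0.25, 0.5, 1 and 2 on the log2 scale were recovered in 66.6%, 88.1%, 98.1% and 99.5% of cases, and 2.80% of the unchanged miRNAs were called. The leukocyte list, lowered by 1 on the log2 scale, was called in 20 of 20 runs, and no other list was called in any of them. The noise was drawn independently for each miRNA. In the real data the estimated correlation within the leukocyte list was 0.515, so these runs do not show how often camera calls a list wrongly.

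Names of miRNAs are those of the array's design. For 309 of the 316 tested miRNAs a gene was found by name in a RefSeq table on GRCm38, used here for names and for the genes in which miRNA genes lie. Genome positions are those of the array design, whose build is mm9 per the file headers. For 7 of the 177 tested miRNAs with both a position and a RefSeq gene, the position lay inside the GRCm38 gene, so the build of those positions is in doubt and they are not printed. Whether a miRNA gene lies in an intron or an exon of its host gene was not analysed here.

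Alternatives changed the background correction, the signal summary, the spot and probe summary, the scaling, the filter, the floor, the test, a replicate block, the authors' value table, and the set of arrays, each left out in turn. Some changed several choices together: normexp, with an offset of 50, was run on the mean and background signals in place of the processed signal, and medians over spots were combined with means of log2 values over probes. The replicate numbers were checked for pairing before the fits were compared, and they do not pair the samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.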

Results

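The study compared miRNA levels in the kidneys of db/db mice, which lack a functional leptin receptor and become obese and diabetic, with those of age-matched control mice. Each group had 4 samples from males aged 28 weeks. The array carried 1881 mouse miRNAs, of which 390 were detected on at least 1 array and 269 on all 8. The number detected was 324 ± 19.9 per control array and 332.5 ± 30.0 per db/db array (SD, n = 4 each), a difference of 8.25 that did not exceed the spread (exact permutation test, 2-sided, p = 0.657). Before scaling, the log2 75th percentile of the miRNAs detected on all arrays was 8.52 ± 0.11 in control and 8.65 ± 0.07 in db/db kidneys (SD, n = 4 each; exact permutation test, 2-sided, p = 0.0857). Across miRNAs, which are not independent replicates, correlations of log2 values were 0.989 to 0.997 within a group and 0.964 to 0.979 between the groups.

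Kidneys of db/db mice had much more miR-122-5p, the dominant miRNA of hepatocytes, and more miR-802-5p and miR-204-5p than control kidneys. They had less of a group of miRNAs typical of leukocytes, with miR-146a-5p, miR-142a-5p and miR-150-5p falling the most among them. Of the 316 tested miRNAs, 41.8% passed the threshold, with 77 higher and 55 lower in db/db kidneys (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05). Most changes were small, with a median size of 0.41 on the log2 scale among those that passed. A fold of 2 or more was reached by 24 of them, 19 higher and 5 lower. Among the 19 were the 11 dim miRNAs described below, for which cross-hybridisation is a candidate explanation. The 2 groups did not overlap for 131 of the 316 miRNAs, or 41.5%, against 2.86% by chance.

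The share of higher among called miRNAs, 58.3%, depended on the scaling. It was 78.1% with no scaling, where the median change of all tested miRNAs moved from -0.02 to 0.10, 83.4% with scaling to labelling spike-ins, where that median was 0.16, and 44.5% with quantile normalization. With the 75th percentile taken over all 1881 miRNAs the count fell to 34, and without db/db replicate 2 the lower miRNAs numbered 84 and 45.1% of the called ones were higher.

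**Figure D1:**
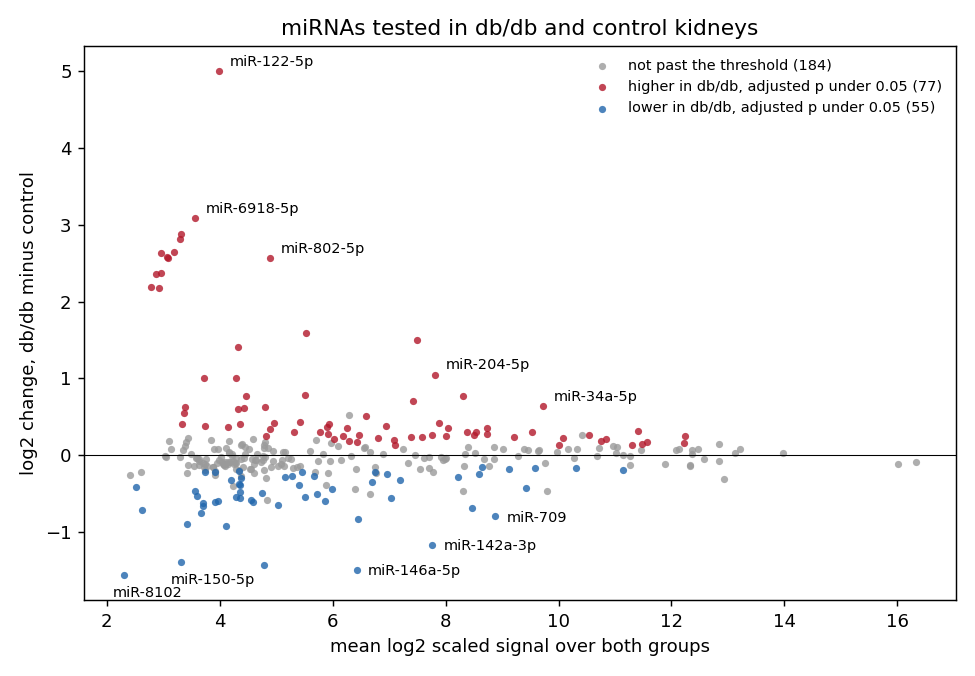
Each point is 1 of the 316 tested miRNAs, with its mean log2 scaled signal over both groups on the x axis and its log2 change, db/db minus control, on the y axis. The 77 red points are higher and the 55 blue points lower in db/db kidneys at an adjusted p under 0.05; miR-122-5p lies at 5.00 and miR-146a-5p at -1.49.

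The miRNA miR-122-5p was detected on all 4 db/db arrays and on no control array. Its log2 signal was 6.48 ± 0.61 in db/db kidneys (SD, n = 4) and lay at the floor of 1.48 in each control, so that it was at least 20.9-fold higher (limma with Benjamini-Hochberg adjustment, adjusted p = 7.49e-06). Its probes map to chromosome 18, 65408523 to 65408541 (mm9). miR-802-5p, a miRNA of liver, pancreas and kidney that is known to rise in obese mice, rose from 3.61 ± 0.08 to 6.18 ± 0.28 (SD, n = 4 each), a 5.93-fold change with adjusted p = 7.49e-06 in limma with Benjamini-Hochberg adjustment; it was detected on 3 control arrays and maps to chromosome 16, 93369983 to 93370003 (mm9). Across the alternatives its call held in each of 25 settings, with a change between 0.72 under normexp and 4.38 in the authors' value table. For miR-122-5p the fitted change lay between 1.10 and 8.46 under those 2 settings, and its call held in each of 25 settings. The upper values, 4.38 and 8.46, include the fill for control arrays on which the miRNA was undetected. miR-204-5p, abundant in tubular epithelium and encoded within Trpm3, rose from 7.29 ± 0.04 to 8.34 ± 0.04 (SD, n = 4 each), a 2.07-fold change and the miRNA with the smallest adjusted p of all tested, 1.94e-06 in limma with Benjamini-Hochberg adjustment. It maps to chromosome 19, 22825104 to 22825121 (mm9). miR-34a-5p, a target of p53, rose by 0.64 ± 0.09 (SE) on the log2 scale, from 9.40 ± 0.08 to 10.04 ± 0.18 (SD, n = 4 each; limma with Benjamini-Hochberg adjustment, adjusted p = 0.000922).

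Of 8 tested leukocyte miRNAs, 6 fell, none rose and 2 did not pass the test; adjusted over the list alone, 7 fell. miR-142a-3p and miR-142a-5p, the arms of a hairpin expressed in blood cells, fell by 1.16 ± 0.16 and 1.43 ± 0.19 (SE) on the log2 scale. miR-150-5p, high in mature lymphocytes, fell by 1.39 ± 0.16 (SE) and was detected on 1 db/db array. miR-223-3p, high in myeloid cells, fell by 0.83 ± 0.09 (SE), from 6.87 ± 0.09 to 6.04 ± 0.17 (SD, n = 4 each). miR-146a-5p, which NF-kB induces in immune cells, fell from 7.17 ± 0.11 to 5.69 ± 0.27 (SD, n = 4 each) and was 2.80-fold lower in db/db kidneys (limma with Benjamini-Hochberg adjustment, adjusted p = 0.000137). It maps to chromosome 11, 43187909 to 43187925 (mm9). The median change of the list was -0.99, and camera called the list lower (Benjamini-Hochberg adjusted p = 0.000598). Camera did so in all 25 alternative settings, with adjusted p from 1.36e-07 to 0.00825. With an estimated correlation the adjusted p of camera was 0.715 and the raw p 0.0890. By fry, which does not compare the list with other miRNAs, the Benjamini-Hochberg adjusted p was 0.000640. miR-155-5p, with a change of -0.22, and miR-146b-5p, with -0.02, were the members that did not pass; both were added here after their values were seen. miR-5107-5p, whose gene lies within Cd74, the invariant chain of MHC class II molecules, fell by 0.92 ± 0.18 (SE) on the log2 scale. In the authors' value table its change was larger, -2.54, and not past the threshold (adjusted p = 0.147 in limma with Benjamini-Hochberg adjustment). It was detected on 3 db/db arrays, and the larger change includes the fill for the undetected one.

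**Figure D2:**
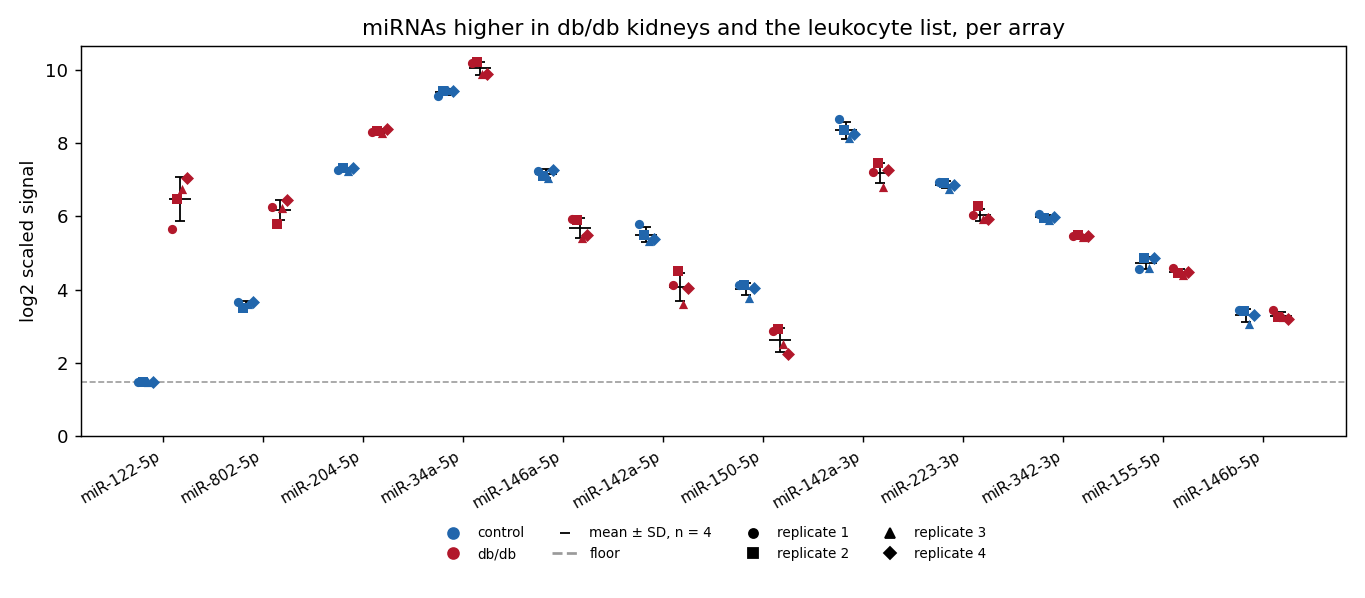
Log2 scaled signal of 12 miRNAs on each array, control in blue and db/db in red, with a marker for each replicate number, the mean and SD of 4 arrays in black and the floor of 1.48 as a dashed line. miR-122-5p sits at the floor in all 4 controls, and for miR-146a-5p, miR-142a-5p, miR-150-5p, miR-142a-3p and miR-223-3p every db/db value lies below every control value.

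Most markers of other cell types did not pass the test. The erythroid miRNAs miR-451a and miR-144-3p varied widely within both groups: log2 miR-451a was 10.29 ± 0.91 in control and 10.55 ± 1.05 in db/db kidneys (SD, n = 4 each; limma with Benjamini-Hochberg adjustment, adjusted p = 0.735). None of 4 tested endothelial miRNAs passed the test, miR-126a-3p with a change of -0.11 and miR-126a-5p with -0.15; both passed as lower under some alternatives, miR-126a-3p under limma with trend and robust fitting (Benjamini-Hochberg adjusted p = 0.0137) and miR-126a-5p in the authors' value table (0.0104). The median of the list was -0.03 and turned to 0.06 with quantile normalization; it was 0.10 with no scaling and 0.15 with spike-in scaling, which move all miRNAs alike, and relative to the median of all tested miRNAs it stayed at -0.01 under both. Neither of the 2 tested smooth muscle and pericyte miRNAs passed, miR-143-3p with -0.04 and miR-145a-5p with -0.06. The striated muscle list had 1 tested member, miR-1a-3p, with a change of 0.37 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0448). Its call held in 10 of 26 alternatives, and under normexp its change shrank to -0.0093 ± 0.045 (SE). Of the list of liver, islet and neuronal miRNAs, miR-122-5p alone rose among 4 tested, and miR-9-5p, miR-128-3p and miR-7a-5p had changes of 0.15, 0.08 and 0.02; the median was 0.12 and the mean 1.31, and under normexp the median was -0.04.

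All 7 members of the list for the miR-30 family, abundant in tubules and podocytes, rose, by 0.15 to 0.30 on the log2 scale. The list does not hold the 3p arms miR-30b-3p, miR-30c-1-3p, miR-30c-2-3p and miR-30d-3p, which were also tested. Of these, miR-30c-1-3p passed the threshold, in a direction not given here, and the others did not. Only miR-30d-3p among them was named by the rule, and its change of 0.08 did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.279). miR-30d-5p rose from 9.38 ± 0.01 to 9.69 ± 0.03 (SD, n = 4 each; limma with Benjamini-Hochberg adjustment, adjusted p = 0.000420), and miR-30c-5p from 12.12 ± 0.07 to 12.37 ± 0.05. Without db/db replicate 2, miR-30a-5p and miR-30e-5p were no longer past the threshold (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0626 and 0.0817). The median change of the list was 0.26, and camera called it higher (Benjamini-Hochberg adjusted p = 0.00619). With an estimated correlation the adjusted p of camera was 0.715 and the raw p 0.171. By fry, which does not compare the list with other miRNAs, the Benjamini-Hochberg adjusted p was 0.000640. The camera call was lost under 4 of the 25 alternatives, all of them scalings, with a median between 0.20 and 0.44.

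Other epithelial miRNAs changed in part. Of 8 tested tubule-enriched miRNAs, 3 rose: miR-204-5p, miR-10b-5p and miR-10a-5p, the last 2 by 0.27 and 0.21 on the log2 scale and encoded in the Hox clusters. The call of miR-10a-5p held in 17 of 26 alternatives and was lost with any of 5 arrays left out, with the highest adjusted p of 0.0934 without db/db replicate 2 (limma with Benjamini-Hochberg adjustment). The median of the list was 0.10. miR-192-5p, the most studied miRNA of the diabetic kidney, was 12.10 ± 0.07 in control and 12.17 ± 0.04 in db/db kidneys (SD, n = 4 each) and did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.216). In the miR-200 family, which represses the ZEB factors of epithelial-mesenchymal transition, miR-200c-3p rose by 0.42 ± 0.08 (SE) and miR-141-3p, of the same cluster, by 0.36 ± 0.07 (SE), while miR-429-3p and miR-200b-3p had changes of 0.10 and 0.07 and did not pass; 2 of 5 tested rose and the median was 0.10. In the list for the miR-23-27-24 clusters, miR-23b-3p rose by 0.32 ± 0.03 (SE) and miR-27b-3p by 0.23 ± 0.04 (SE). The other 3 tested members of the list did not pass, with a median of 0.11 over all 5. The list does not hold the 5p arms miR-24-1-5p and miR-24-2-5p, which were also tested. Of these arms, miR-24-1-5p passed the threshold, in a direction not given here, and miR-24-2-5p did not. Of the 9 let-7 miRNAs, with a median of 0.02 that was -0.03 in the authors' value table (0.04 and 0.06 relative to all tested miRNAs), let-7d-5p rose, by 0.17, and its call was lost without db/db replicate 2 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0889). None of the 3 miR-29 miRNAs, repressors of collagen mRNAs, passed, with a median of 0.07 and changes of 0.08, 0.07 and -0.05 for miR-29b-3p, miR-29c-3p and miR-29a-3p.

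Fibrosis-associated miRNAs moved both ways. Of 11 tested, 3 rose and 4 fell; adjusted over the list alone, 4 rose and 5 fell. The rising ones were miR-34a-5p, miR-34c-5p and miR-34b-5p, the last 2 by 0.38 and 0.34 and added after their values were seen. Falling ones were miR-132-3p, by 0.75 ± 0.13 (SE), and miR-214-3p, whose gene lies within Dnm3os, by 0.44 ± 0.08 (SE). So did miR-199a-3p and miR-199a-5p, by 0.42 ± 0.06 and 0.32 ± 0.08 (SE). By name, their genes lie at 2 loci, of which 1 is Dnm3os. The array design maps miR-199a-3p to chromosome 2, 32174047 to 32174065 (mm9), near miR-199b-5p, so its signal is not particular to those 2 loci. The median of the list was -0.17, and 0.02 with spike-in scaling, with -0.14 relative to all tested miRNAs in both. In the authors' value table miR-132-3p had a larger change, -2.06, that was not past the threshold (adjusted p = 0.187 in limma with Benjamini-Hochberg adjustment). It was detected on 3 db/db arrays, and the larger change includes the fill for the undetected one.

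Among miRNAs tied to cell growth, the cluster of miR-17 to miR-92a and its paralogs had 5 falling and no rising members of 10, led by miR-19a-3p, which fell by 0.35 ± 0.06 (SE); the median was -0.11, and 0.02 with no scaling and 0.07 with spike-in scaling, but relative to all tested miRNAs it was -0.09 in all 3. Of these calls, miR-17-5p held in 11, miR-19b-3p in 14 and miR-18a-5p in 19 of 26 alternatives, each of them lost with any of several single arrays left out. In the miR-15/16 family 3 of 7 rose and 2 fell, and adjusted over the list alone 3 rose and 3 fell. miR-322-5p and miR-503-5p, neighbours on chromosome X that restrain the cell cycle, rose by 0.36 ± 0.05 and 0.55 ± 0.12 (SE), the call of miR-503-5p holding in 19 of 25 alternatives with a change of -0.01 under normexp. miR-16-5p fell by 0.19 ± 0.05 (SE), a call that held in 20 of 26 alternatives; it was lost without control replicate 2, db/db replicate 1 or db/db replicate 3, and the change was -0.06 with no scaling and -0.0036 with spike-in scaling. The median of this list was -0.01 and its mean 0.09, and camera's direction was up without passing. In the miR-181 family miR-181b-5p and miR-181a-5p rose by 0.31 and 0.23, and miR-181c-5p and miR-181d-5p, with -0.08 and -0.13, did not pass; the median was 0.08 and -0.00 under normexp.

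Of 13 tested miRNAs of insulin and lipid metabolism, 5 rose and 1 fell, with a median of 0.07. Besides miR-802-5p, miR-335-5p rose by 0.62 ± 0.13 (SE), turning to -0.01 under normexp, and miR-193b-3p by 0.28 ± 0.08 (SE), a call that held in 15 of 26 alternatives and was lost with any of 6 arrays left out, while miR-148a-3p fell by 0.49 ± 0.07 (SE). The fixed list for the Dlk1-Dio3 locus had 1 tested member, miR-494-3p, which fell by 0.68 ± 0.18 (SE). It does not hold miR-3072-5p, miR-1906 and miR-3544-3p, which were also tested and whose genes lie within Mirg, Meg3 and Rtl1. The locus as a whole was thus not assessed. Of 100 tested miRNAs numbered 1000 and above, 19 rose and 19 fell; adjusted over the list alone, 19 rose and 17 fell. The median of that list was -0.11 and its mean 0.12, and camera's direction was down without passing. With no scaling the median was 0.01 and with spike-in scaling 0.07, but relative to all tested miRNAs it was -0.09 in all 3. For the 13 tested lists other than the leukocyte and miR-30 lists, camera gave Benjamini-Hochberg adjusted p from 0.0734 to 0.876. Some of these lists passed by fry, which does not compare a list with other miRNAs. Its Benjamini-Hochberg adjusted p was 0.000640 for the tubule-enriched list and for the list of liver, islet and neuronal miRNAs. It was 0.00406 for insulin and lipid metabolism and for the list led by miR-23b-3p. For the miR-200 family it was 0.0115, and for the list led by miR-19a-3p 0.0360. For the rest it ranged from 0.0939 to 0.529. For every list not named above with a second count, the count adjusted over the list alone was equal to that over all miRNAs.

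**Figure D3:**
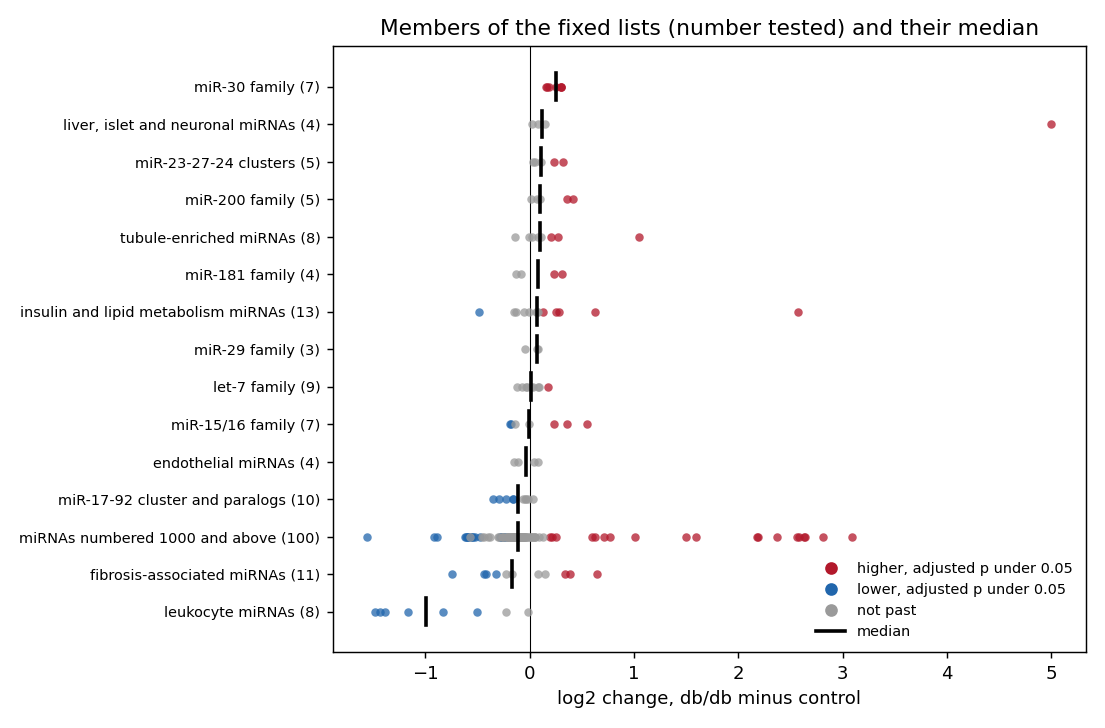
Each point is a tested miRNA at its log2 change, db/db minus control, on the x axis, in the row of its list, with the number tested in brackets and the list's median as a black bar. Among the 15 lists with 3 or more tested members, the only ones drawn, the leukocyte list has the lowest median, -0.99, and the miR-30 family the highest, 0.26.

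A set of dim miRNAs appeared in db/db kidneys. miR-6918-5p, miR-504-3p, miR-7080-5p, miR-7682-3p, miR-6904-5p, miR-6401, miR-7218-5p, miR-3070-2-3p, miR-129b-5p and miR-6980-5p rose by 2.19 to 3.09 on the log2 scale from values at or near the floor, and were among the 12 largest increases. The size of these changes depended on the signal used, from 0.15 for miR-6980-5p to 0.42 for miR-6918-5p under normexp, and from 5.49 for miR-7080-5p to 6.73 for miR-504-3p in the authors' value table. The value-table changes include the fill for control arrays on which these miRNAs were undetected. miR-6975-5p, which rose by 2.18, was added after its values were seen. Of these 11 miRNAs, 9 were detected on no control array, and for those the signal was at least 3.22-fold to at least 5.24-fold higher; miR-6918-5p and miR-7080-5p were detected on 1 control array. In control replicate 3 all 11 lay between the other controls and the db/db kidneys, at 9.33% to 32.2% of the rise in signal. Their probes were rich in C, 48.6% against 28.4% for other tested miRNAs, and poor in G, 8.25% against 25.2%. The 3p arms miR-7080-3p and miR-6980-3p had changes of -0.09 and -0.16 and did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.467 and 0.251). With a floor 4 times as high, miR-6980-5p was no longer past the threshold (adjusted p = 0.0708 in limma with Benjamini-Hochberg adjustment). When an array was left out, the change ranged from 2.59 to 4.35 for miR-6918-5p and from 1.73 to 3.13 for miR-6980-5p.

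**Figure D4:**
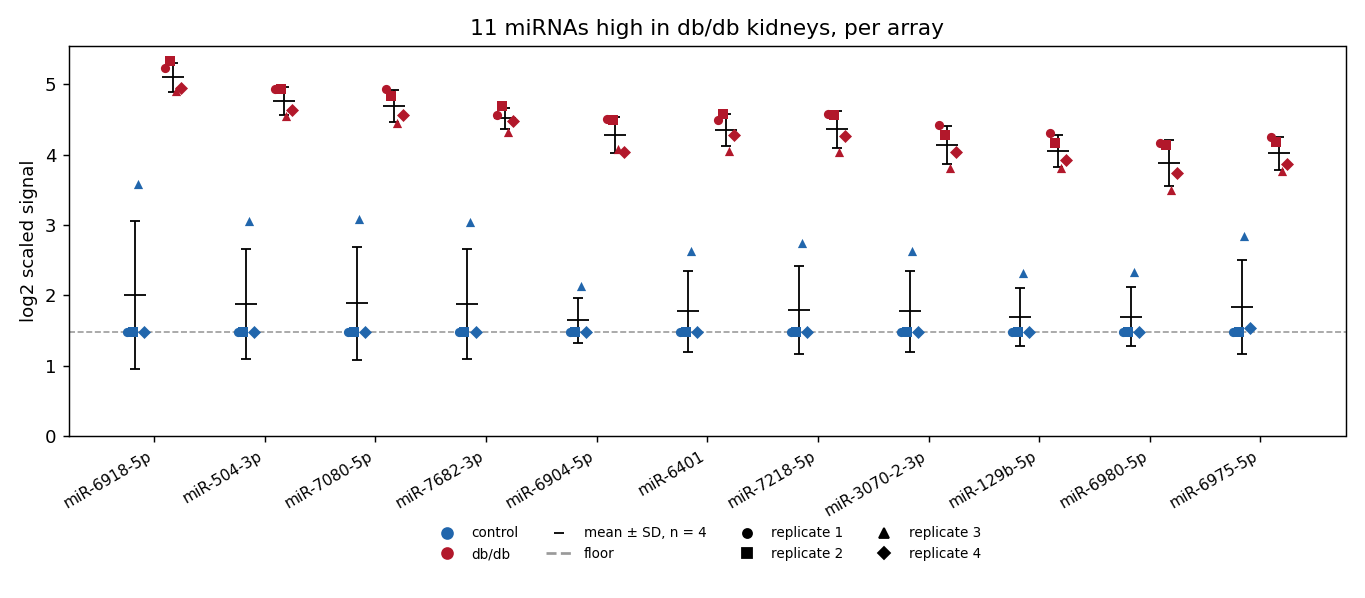
Log2 scaled signal of the 11 miRNAs on each array, control in blue and db/db in red, with a marker for each replicate number, the mean and SD of 4 arrays in black and the floor of 1.48 as a dashed line. The triangle of control replicate 3 lies above the other 3 controls and below the 4 db/db arrays for each of the 11.

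The remaining large decreases were of other kinds. miR-8102, detected on all control arrays and on no db/db array, was at least 2.43-fold lower, a difference that vanished with a floor 4 times as high (adjusted p = 0.575, limma with Benjamini-Hochberg adjustment). miR-709 fell from 9.28 ± 0.05 to 8.49 ± 0.10 (SD, n = 4 each) and was 1.73-fold lower (limma with Benjamini-Hochberg adjustment, adjusted p = 5.81e-05). miR-3082-5p and miR-466f-3p, whose probes hold GT or CA repeats, fell by 0.89 ± 0.22 and 0.71 ± 0.18 (SE), and neither was past the threshold with a floor 4 times as high, where the changes shrank to -0.40 and 0, or in the authors' value table, where they grew to -3.30 and -1.79. These 2 miRNAs were detected on 2 and 3 db/db arrays, so their larger changes in the value table include the fill for undetected arrays. Slide row and genotype coincide on this slide, and the controls' genotype is labelled in 2 ways.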

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

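All tests of the 3 patterns below, with the bounds of their labels and the minimum of 6 shared bases, were chosen only after the results were seen; the outlier check was set beforehand.

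A value far from the other 3 of its group was found 12 times among 91 miRNAs and 2 array measures in 2 groups, where chance gives about 9.3 such values. In control replicate 3 a high value stood alone for 10 of them: 3.59 for miR-6918-5p, 3.05 for miR-504-3p, 3.09 for miR-7080-5p, 3.04 for miR-7682-3p, 2.13 for miR-6904-5p, 2.64 for miR-6401, 2.74 for miR-7218-5p, 2.63 for miR-3070-2-3p, 2.31 for miR-129b-5p and 2.33 for miR-6980-5p, with the other controls at the floor of 1.48, which makes any value above it stand apart. miR-322-5p was low in control replicate 1, at 8.43 against 8.58 to 8.59 in the other controls. miR-6980-3p was low in db/db replicate 4, at 3.60 against 3.86 to 3.90 in the other db/db kidneys.

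For the 11 dim miRNAs, chosen for being high in db/db kidneys and above the floor in control replicate 3, mixing of db/db RNA into that control is argued against: at the median share of 22.4%, miR-802-5p should have reached 4.70 there, and it was 3.62, beside a mean of 3.61 ± 0.10 (SD) in the other 3 controls. miR-146a-5p, miR-142a-5p and miR-142a-3p lay near the levels that mixing predicts, at 7.05, 5.34 and 8.15 against 6.99, 5.35 and 8.23, but there the prediction lies close to the other controls (7.21, 5.56 and 8.42), so these 3 do not outweigh miR-802-5p. A candidate explanation is cross-hybridisation of an RNA that carries the telomeric repeat. The probes of the 11 share runs with CCCTAA repeats of 5.09 bases on average. The mean was 3.64 for the 70 tested miRNAs with a probe C content within the range of the 11, the 11 included. Outside the 11, 16 miRNAs on the array had probes that share 6 or more bases with that repeat. They were higher in db/db kidneys by 0.77 on average, and 14 lay above 0. The mean was 0.00 for the 1043 others whose probe C content lay within the range of these 16. That range took in much of the array, so C content was not closely matched. A permutation test gave p = 1e-05, the smallest that 100000 resamples can give, for probes that are alike and not independent. The cut of 6 bases lies above the mean run of the 11. Outside the 11, the 72 miRNAs with a longest run of 5 bases changed by 0.10 on average. No filter for detection was set, and 390 of 1881 miRNAs were detected on any array. Most of the 1043 were thus undetected, which holds their change near 0, so the p does not weigh the match alone. In control replicate 3 the 16 were higher than in the other controls by 0.20 on average. Only 6 of the 16 lay above 0, where a miRNA at the floor on all controls counts as 0. Genotype, slide row and an RNA of another sequence stay open.

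The fall of leukocyte miRNAs was weighed next. There was no sign of less blood left in db/db kidneys: miR-451a was not lower there, with a change of 0.27 ± 0.61 (SE), though it varied widely. With miR-451a as a covariate the median change of the list was -1.03. A covariate that differs so little between the groups could hardly shrink the fall, so that fit does not decide the question. Scaling as the whole cause is argued against: over 7 other scalings and signal summaries the median fell least under normexp, to -0.36. Camera with its preset correlation called the list in each. With an estimated correlation the list did not pass in the fit reported (Benjamini-Hochberg adjusted p = 0.715). Fewer leukocytes in db/db kidneys may account for the fall, but this cannot be told apart from lower expression within cells, since members changed unequally, from -1.49 for miR-146a-5p to -0.0170 for miR-146b-5p, and which of them kidney cells also express was not measured.

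The rise of miR-122-5p was weighed last. The RNA behind the 11 dim miRNAs is argued against as its cause, since at their median share miR-122-5p should have reached 4.55 in control replicate 3, and it lay at the floor of 1.48. Traces of liver RNA in the db/db samples, or miRNA taken up from blood, may also raise it. miR-148a-3p, which liver holds too, had a change of -0.49, but kidney holds it as well and a small share of liver RNA need not move it. miR-802-5p, found in liver and in kidney, rose 5.93-fold, so that liver RNA and expression in the kidney cannot be told apart here.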

How the results depend on the processing

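Spike-in scaling, the miR-451a covariate and the fit without the 11 dim miRNAs were chosen after seeing the data; all other alternatives were fixed before the data were examined. The count of called miRNAs (77 higher, 55 lower) moved most with the 75th percentile over all miRNAs, to 34 (23 higher, 11 lower); that percentile lay between 2.31 and 4.14 signal units, near the SD of negative control spots, so it scales arrays by background. The number of lower miRNAs was 86 with quantile normalization and 28 with no scaling; spike-in scaling gave 169 calls, 28 lower and the rest (1.4e+02, rounded) higher; the cause was not tested. With an array left out, the total ranged from 114 to 153, the higher from 69 to 82 and the lower from 42 to 84, the last without db/db replicate 2, which had the fewest detected miRNAs, 289. The number of lists called, 2, became 6 under normexp and 1 with no scaling, and was 2 to 3 with an array left out; the cause was not tested. The median of the miR-30 family stayed positive and its camera call was lost with the 75th percentile over all miRNAs (0.27, adjusted p = 0.987), quantile normalization (0.20, 0.0533), no scaling (0.38, 0.102) and spike-in scaling (0.44, 0.119), by limma's camera with Benjamini-Hochberg adjustment; it ranged from 0.21 to 0.28 with an array left out. The leukocyte list kept its call by camera with the preset correlation in all 25 settings, but not with an estimated correlation (Benjamini-Hochberg adjusted p = 0.715), with medians from -1.25 to -0.36, and from -1.14 to -0.91 with an array left out.

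Signs turned for miR-30d-3p (-0.59) under quantile normalization. They also turned for miR-19b-3p (0.0215) and the list of miRNAs numbered 1000 and above (0.0705) under spike-in scaling, which shifts all values up. Under normexp, which changed the signal and the background correction together, miR-1a-3p (-0.0093), miR-503-5p (-0.0083) and miR-335-5p (-0.0071) fell just below 0. Each of these lay within its SE (0.045, 0.046 and 0.041), so the changes shrank to about 0 rather than reversed, and the cause was not tested. Of 56 named calls, 18 held under every setting in which the miRNA had a value (24 to 26 settings), 32 were lost with the 75th percentile over all miRNAs, 13 of them under no other setting, and 11 with an array left out. Of 35 named miRNAs not called, 26 passed under at least 1 alternative. The differences in detected miRNAs and in overall signal ranged from -0.25 to 22.75 and from 0.09 to 0.21 when an array was left out; without control replicate 4 the overall signal of the other controls lay wholly below that of the db/db arrays, and a permutation test of so few arrays cannot show that the difference is stable. Without the 11 dim miRNAs 121 miRNAs were called, 66 higher and 55 lower.

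Samples with the same replicate number did not deviate together (correlations -0.43, 0.41, -0.05 and -0.07), so the numbers were not taken as pairs. With the replicate block 81 miRNAs were called higher and 63 lower. Signal over background limits the dim miRNAs, whose changes depend on the floor.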

Other observations

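The GT and CA repeat probes were picked out only after the result was seen, and the tests of 2 single lists over splits of the arrays were added after the count of lists over splits was seen; the other tests over splits were planned.

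Members of the large miR-466 and miR-467 families and others with GT or CA repeats in their probes were mostly lower in db/db kidneys. Of 10 such tested miRNAs, 9 passed and were lower and none was higher, with a median change of -0.60. They included miR-467f, which fell by 0.59 on the log2 scale, miR-466q by 0.66, miR-669p-3p by 0.54, miR-574-5p by 0.64 and miR-1187 by 0.62, all named after their values were seen. These probes are alike in sequence, so the miRNAs do not count as independent observations.

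Of the 35 splits of the 8 arrays into 4 and 4, the real one alone called any miRNA, 1 of 35, so a random split of the arrays does not account for the count, though the split by genotype is also the split by slide row. For the number of lists this is not so: 14 of the 35 splits gave 2 or more, and the highest of the others gave 5. The leukocyte list had its smallest camera p, 3.99e-05, in the real split, 1 of 35, with 8.41e-05 the smallest of the others. For the miR-30 family, 7 of 35 splits gave a camera p as small as the real 0.000825, the smallest of the others being 5.41e-05, so its shift as a list cannot be told from that of a random split.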
